A study of Mus musculus with 10 samples.

How the data were processed

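Brown adipose tissue, the heat-producing fat depot of rodents, was profiled in 10 mice with Affymetrix expression arrays, on which each transcript is read by sets of short probes. Per the labels' protocols, the mice were untreated littermates aged about 1 year, and their genetic background was 129. Of these, 5 were wild type (WT) and 5 were labelled as knockouts (KO) of Sirt3, which encodes a mitochondrial deacetylase. Per the labels, total RNA was extracted with Trizol, cleaned on a column, and 6 ug of it was used to make biotinylated cRNA. Groups and replicate numbers were taken from the sample titles, and each array was treated as a separate mouse, since the protocol text speaks of littermate mice.

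The deposited values are log2 signals, and per the submitters' processing notes they were made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a set. The RMA software, its version and its settings are not given in the sources used here. The log2 scale was read from the values: array medians lay between 5.58 and 5.61. RMA makes array distributions alike by construction, so a change shared by most transcripts would not be visible. RMA also gives every probe set a value, with no detection call, so low signals have no stated floor. The number of arrays limits the precision.

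The table held 45101 probe sets, of which 64 were controls. Of the others, 34945 had 1 gene in the platform annotation, 932 had several and 9160 had none; 34741 of those with 1 gene matched the RefSeq gene table of assembly GRCm38.p6 by gene ID. That table was used for names and gene order, and no coordinates are given because the study names no build. Probe sets with several genes or none were left out, and the probe set with the highest mean over all 10 arrays was kept for each gene, which left 18193 genes. Among fixed list members lost this way were Gapdh, Gpi1 and Eno1, which are not analysed here.

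Differences are KO minus WT, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates. P-values were adjusted by Benjamini and Hochberg over all genes, and genes with an adjusted p under 0.05 were called. Errors beside differences are standard errors of that fit, and intervals are 95% confidence intervals from it. Single values were compared by exact two-sided permutation over the 252 ways of choosing 5 of 10 arrays. Gene lists were compared with the other genes by camera of limma with its preset correlation between genes of 0.01, adjusted over the 39 of 40 fixed lists with at least 5 measured members. Camera with a correlation estimated per list, and fry, were run as alternatives; the estimated correlation was also run in the fits that left out arrays, with the mean of all probe sets and with the muscle covariate, after the data were seen. The design, the 40 gene lists, the rule for named genes and most alternatives were set before the data were examined.

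Named genes are the 7 sirtuins; the 10 genes per direction with the largest change among called genes with non-overlapping groups, with places left open filled by the smallest unadjusted p, skipping unnamed sequences; Slc2a1, Hk2, Pgk1, Pdk1, Ldha, Vegfa, Hif1a and Ucp1; and up to 4 members with the smallest unadjusted p of each list described. The choice of lists to be described with up to 2 members each was made after the values were seen. Alternatives included another quantile normalization, centring of arrays, a filter on dim genes, other variance models, array weights, other choices of probe set (among them none named _s_at, _x_at or _a_at, suffixes of sets that match several transcripts, in _a_at those of the same gene), the replicate number as a block, and leaving out each array in turn. A covariate for skeletal muscle transcripts and 2 fits that left out arrays were added after the data were seen. The 3'/5' check first covered Actb, Gapdh and Pcx; Tfrc and 18S RNA were added after the Pcx values were seen.

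The fit was tested on simulated values for 18193 genes in 5 against 5 arrays. Of 100 genes changed by 0.5 log2 units it called 81%, and of 100 changed by 1 log2 unit it called 96%, with 12 false calls among 189. The noise was drawn independently for each gene, and both sets of genes were changed in the same simulated data. Real arrays hold structure shared between genes, so these shares check the fit and do not give its power in the real comparison. Figures were drawn with matplotlib 3.10.9.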

Results

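Expression was measured in brown adipose tissue of 5 WT mice and 5 mice labelled Sirt3 KO, 1 array per mouse. All 10 arrays resembled each other, with pairwise correlations across probe sets from 0.988 to 0.997, and no array duplicated another. The comparison asks which transcripts differ between genotypes. The title of the study names SIRT3, HIF1a and the metabolism of cancer cells, so glycolysis genes and targets of the hypoxia-induced factor HIF1 were examined as groups of their own.

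Sirt3 was read by 1 probe set (1417892_a_at), and its signal was not lower in the arrays labelled Sirt3 KO. The mean log2 signal was 10.32 ± 0.07 (SD, n = 5) in arrays labelled KO and 10.13 ± 0.10 (SD, n = 5) in WT. The difference was 0.19 ± 0.061 log2 units (95% confidence interval 0.06 to 0.32), and all 5 KO arrays lay above the WT mean. WT arrays 1 to 5 gave 10.10, 10.28, 10.19, 10.07 and 10.03, and KO arrays 1 to 5 gave 10.39, 10.29, 10.40, 10.22 and 10.31. An exact two-sided permutation test of the n = 5 against 5 values gave p = 0.016 before adjustment, while the adjusted p of limma over all genes was 0.914. The part of the gene that was deleted is not given in the sources used here, and a probe set outside that part would not check the labels. Directions below therefore refer to arrays labelled Sirt3 KO. The other sirtuins, a family of NAD-dependent deacylases, gave differences between -0.09 (Sirt2) and 0.07 (Sirt6), and none passed the test. The signs for Sirt1, Sirt4, Sirt5 and Sirt7 turned under some alternatives.

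**Figure D1:**
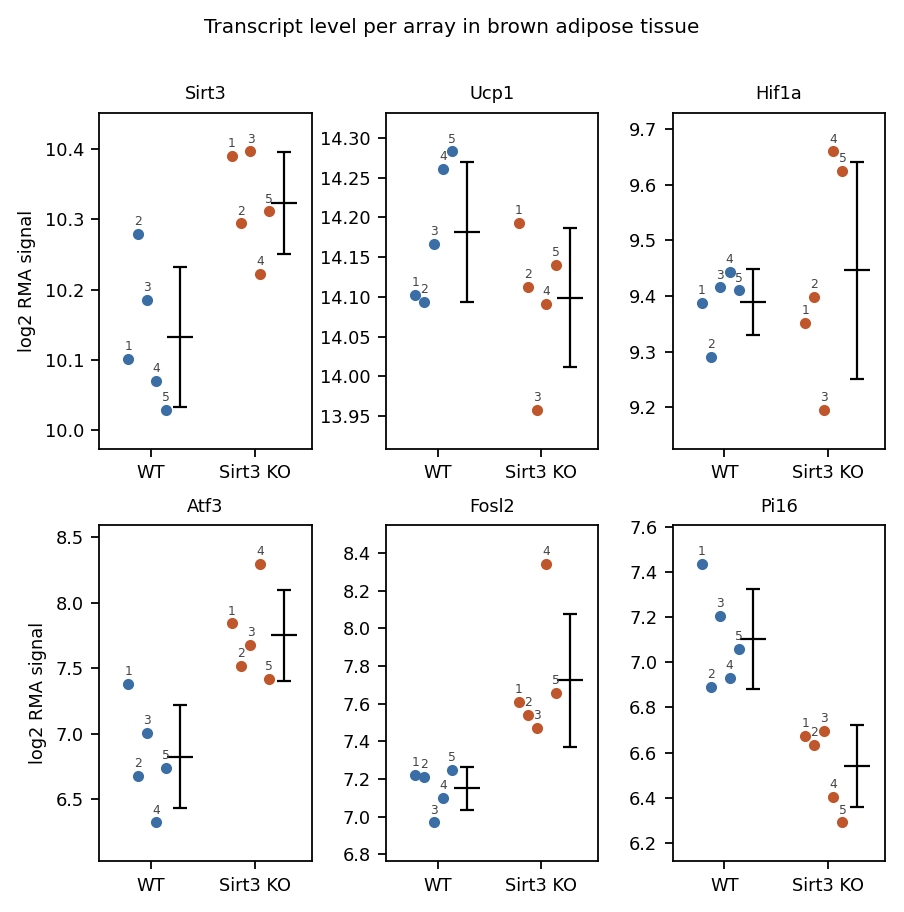
Log2 RMA signal of Sirt3, Ucp1, Hif1a, Atf3, Fosl2 and Pi16 on the vertical axis (not starting at 0) for each array, numbered by replicate and grouped by genotype label, with mean and SD (n = 5) as black bars. Sirt3 spans 0.37 log2 units over the 10 arrays with no array set apart, while the Atf3, Fosl2 and Pi16 values of the 2 groups do not overlap.

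No gene passed the test between arrays labelled Sirt3 KO and WT. The genes nearest to it on the higher side included Itih2 (0.32 ± 0.060, KO minus WT log2 difference ± SE), a heavy chain of the inter-alpha-trypsin inhibitor family. Atf3, a stress-induced transcription factor, differed by 0.93 ± 0.20. Fosl2, a subunit of the AP-1 transcription factor, differed by 0.57 ± 0.15, and Slc6a6, a taurine transporter, by 0.23 ± 0.052. On the lower side, Pi16, a peptidase inhibitor found in fibroblasts, differed by -0.56 ± 0.12, Bclaf1 by -0.36 ± 0.078 and Slc9a9, a sodium/proton exchanger of endosomes, by -0.33 ± 0.071. In each of these 7 genes every KO value lay on one side of every WT value. Itih2 and Slc9a9 were dim, with mean log2 signals of 4.17 and 4.68, below the array medians of 5.58 to 5.61. How far they lay above background is open.

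The other genes with the smallest unadjusted p were Pdzk1, Sntb2, Lcorl, Klf7, Lyrm9 and Cd83 among those higher, with differences from 0.22 (Pdzk1) to 0.52 (Cd83). Those lower were Ctcf, Mycs, Zfp953, Themis3, Cmtm2b, Eid2 and Zfp955a, with differences from -0.25 (Ctcf) to -0.21 (Cmtm2b). Mean log2 signals were also below the array medians for Pdzk1 (4.69), Mycs (4.79), Themis3 (4.79) and Cmtm2b (3.90). Probe sets disagreed for Ctcf, which encodes a chromatin insulator protein: its second probe set gave 0.12. They also disagreed for Lcorl, whose probe sets ranged from -0.18 to 0.47, and a dim probe set of Bclaf1 gave 0.10. A second probe set of Zfp955a gave 0.06, further ones of Slc9a9 gave 0.012 and 0.026, and one of Lyrm9 gave -0.012. Others lay near 0: a second probe set of Pi16 gave -0.011 and 1 of the 4 of Slc6a6 gave 0.010. In all, 16 of the 40 named genes with several probe sets had at least 1 of opposite sign to the one used, among them also Hif1a, Hif1an, Slc2a1, Pdk1, Vegfa, Flt1, Srxn1, Mrpl1, Mrpl35 and Mrpl47.

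By limma, 0 of 18193 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.914. At an unadjusted p under 0.05 there were 851 genes (337 higher, 514 lower), or 4.68%, where chance alone gives 909.65. Groups did not overlap in 114 genes, or 0.627%, where chance gives 0.794%. The median standard deviation within groups was 0.124 log2 units, and the median half-width of the confidence interval was 0.169, before any adjustment over genes. Leaving out WT 2 raised the unadjusted count to 1418, and a covariate for skeletal muscle transcripts, added after the data were seen, raised it to 1521; the adjusted count was 0 in both.

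Glycolysis genes did not shift as a group between arrays labelled Sirt3 KO and WT in the main fit. Of the 16 measured members of the fixed list, 8 were higher and 8 lower, with a median difference of 0.017 log2 units, and 0 passed over all genes or adjusted over the list alone. Hk1, a hexokinase, had the smallest unadjusted p of them at 0.30 ± 0.13, and Pfkfb3, which makes an activator of phosphofructokinase, differed by -0.38 ± 0.20. Pgk1, phosphoglycerate kinase, differed by 0.08 ± 0.050, Pkm, pyruvate kinase, by 0.11 ± 0.087, Hk2 by -0.02 ± 0.089, Ldha, lactate dehydrogenase A, by -0.04 ± 0.045, and the glucose transporter Slc2a1 by -0.02 ± 0.14. The signs for Hk2, Pkm and Slc2a1 turned under some alternatives, and without WT 4 and WT 5, left out after the data were seen, Pfkfb3 differed by -0.035 and Hk1 by 0.11. The list mean was lowest in KO 3 (10.29), WT 5 (10.33), KO 1 (10.36) and WT 4 (10.37). The same arrays were lowest in skeletal muscle transcripts. With the muscle covariate, added after the data were seen, the mean difference went from 0.0076 to 0.051. Genotype and muscle RNA are therefore not separated for this list in the main fit.

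Targets of HIF1 outside glycolysis did not shift either, with 9 of 23 members higher, 14 lower, a median of -0.05 and 0 members past the test over all genes or adjusted over the list alone. Lox, a collagen cross-linking enzyme, differed by 0.43 ± 0.25, Bhlhe40, a transcriptional repressor, by 0.33 ± 0.17, Narf by -0.18 ± 0.10 and Fam162a by -0.09 ± 0.054. Without WT 4 and WT 5 they differed by 0.098, 0.15, -0.051 and -0.054, and the list mean turned from -0.025 to 0.044. The growth factor Vegfa differed by -0.02 ± 0.090, the pyruvate dehydrogenase kinase Pdk1 by 0.03 ± 0.076 and Hif1a itself by 0.06 ± 0.086, and each of these 3 signs turned under some alternatives. The adjusted p of camera was 0.31 for glycolysis and 0.78 for HIF1 targets. Glycolysis reached 0.029 with the muscle covariate (0.66 there with an estimated correlation, or an unadjusted p of 0.058) and 0.037 without KO 3 (0.80 with an estimated correlation), and it was 0.98 without WT 4 and WT 5. Both lists were chosen because the title of the study names their theme, so they are not independent of it.

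**Figure D2:**
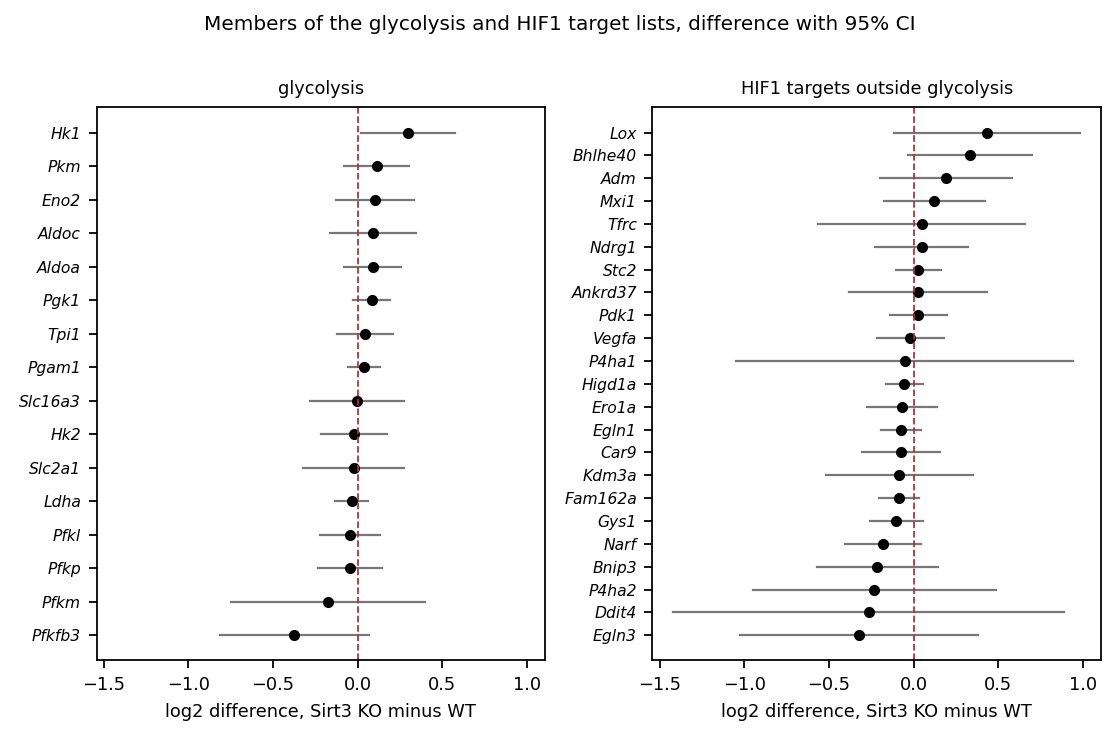
Log2 difference, KO minus WT, on the horizontal axis for each measured member of the glycolysis list (16 genes) and of the list of HIF1 targets outside glycolysis (23 genes); points are estimates of limma and lines their 95% confidence intervals (n = 5 per group). Members lie on both sides of 0, with medians of 0.017 and -0.05.

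Skeletal muscle transcripts were the group with the widest differences between arrays. All 19 members of the fixed list, among them Acta1 (skeletal actin), Myh1 and Myh7 (myosin heavy chains) and Tnnc2 (troponin C), were lower on average in arrays labelled KO, with a median of -1.61 log2 units and 0 members past the test over all genes or adjusted over the list alone. Acta1 differed by -2.15 ± 1.6, Myh1 by -2.40 ± 1.8, Tnnc2 by -2.25 ± 1.7 and Myh7 by -1.14 ± 0.85. The list mean was 10.88, 11.45, 10.84, 9.28 and 7.39 in WT arrays 1 to 5, and 5.53, 10.82, 5.28, 10.79 and 9.78 in KO arrays 1 to 5. The adjusted p of camera was 0.0011, but the adjusted p was 0.87 with an estimated correlation, and an exact permutation test of the list means (n = 5 per group) gave p = 0.26. The call was lost without WT 2 (0.13), without KO 1 (0.25) or without KO 3 (0.29). With the 3 lowest arrays left out (WT 5, KO 1 and KO 3, added after the data were seen) the adjusted p of camera was 0.999. Those arrays were chosen by their low values of this same list, so that fit cannot test its call. Without WT 4 and WT 5 the adjusted p was 3.3e-10, but 0.93 with an estimated correlation in that fit; the mean was -2.62 there, against -1.53 over all arrays and -0.74 without KO 3, and Myh7 was at -2.16 ± 0.84 (-0.32 without WT 2).

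Immediate early and heat shock genes, which are induced within minutes by stimuli and stress, were higher in arrays labelled KO in 15 of 17 members, with a median of 0.33 and a mean of 0.47 log2 units. Atf3 was the 1 member that passed adjusted over the list alone, and 0 passed over all genes. Fosb, an AP-1 subunit, differed by 2.14 ± 0.95, Ier3 by 0.42 ± 0.19 and the heat shock gene Hspa1a by 0.98 ± 0.70 (0.39 without WT 4). Members did not all move together over the WT arrays. In WT 1 and WT 5 the heat shock gene Hspa1b was 7.71 and 11.59, while Fos was 11.53 and 4.49 and Fosb 9.16 and 3.97. In WT 4, Hspa1b (6.88) and Fosb (3.63) were both at their lowest. The adjusted p of camera was 0.0011, and the adjusted p was 0.87 with an estimated correlation; an exact permutation test of the list means (n = 5 per group) gave p = 0.13. Arrays WT 1, at 9.38, and WT 2, at 8.68, lay inside the range of the KO arrays, 8.66 to 9.56. The other WT arrays lay between 8.21 and 8.38. Without WT 4 and WT 5, left out after the data were seen, the adjusted p was 0.017 (0.93 with an estimated correlation in that fit), the mean difference of the list was 0.26 and that of Fosb was 0.82 ± 0.83.

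Ribosomal protein genes were slightly lower in arrays labelled KO, the cytosolic ones mainly through 2 WT arrays: without WT 4 and WT 5 the mean difference went from -0.053 to -0.0056 for the cytosolic list and from -0.059 to -0.039 for the mitochondrial one. Of 76 mitochondrial ribosomal protein genes 61 were lower (median -0.05), among them Mrps18a (-0.24 ± 0.093), Mrpl1 (-0.13 ± 0.054), Mrpl35 (-0.13 ± 0.059) and Mrpl47 (-0.15 ± 0.069). Of 42 cytosolic ribosomal protein genes 38 were lower (median -0.06), among them Rps27 (-0.18 ± 0.068), Rpl37 (-0.19 ± 0.083) and Rpl39 (-0.14 ± 0.074), while Rpl12 differed by 0.22 ± 0.10. The probe sets of Rps27, Rpl12 and Rpl39 had mean log2 signals of 6.62, 6.43 and 7.84, against a cytosolic list mean of 11.08 in WT arrays. How well they read these transcripts is open. Endothelial markers were slightly higher, in 13 of 15 members (median 0.09), mainly through WT 3, without which the mean difference went from 0.11 to 0.030. Esam differed by 0.36 ± 0.15, Flt1 by 0.19 ± 0.13 (0.079 without WT 3) and Cdh5 by 0.13 ± 0.089 (0.066 without WT 3). Vwf went the other way at -0.24 ± 0.11 (-0.13 without WT 4). No member of these 3 lists passed over all genes or adjusted over the list alone. The adjusted p of camera was 0.0011 for each ribosomal list and 0.010 for endothelial markers, and the adjusted p was 0.87 for all 3 with an estimated correlation. The mitochondrial list lost its call without WT 5 (0.063), without KO 4 (0.13), without WT 4 and WT 5 (0.089) and after another quantile normalization (0.13); the cytosolic list lost it without WT 4 (0.15), without WT 4 and WT 5 (0.86) and without probe sets named _s_at, _x_at or _a_at (0.83). Endothelial markers lost it without WT 3 (0.57), without WT 5 (0.085), without the 3 arrays lowest in muscle transcripts (0.089) and without such probe sets (0.066).

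**Figure D3:**
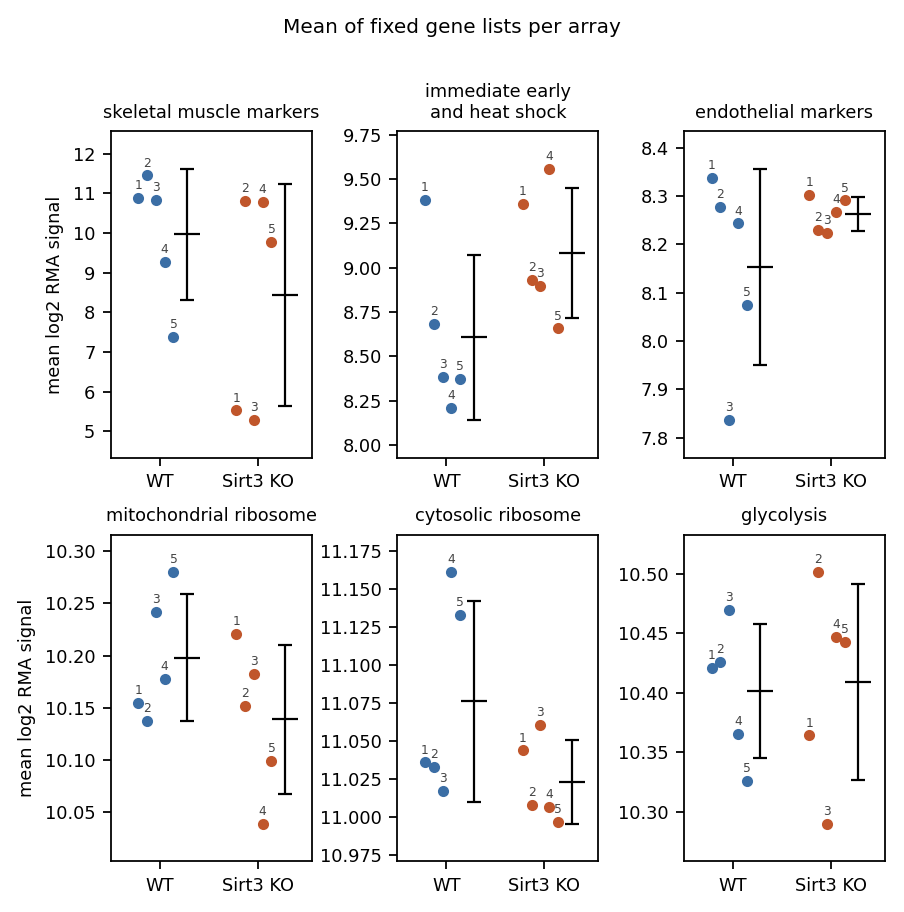
Mean log2 RMA signal of the members of 6 fixed lists on the vertical axis (not starting at 0, different in each panel) for each array, numbered by replicate and grouped by genotype label, with mean and SD (n = 5) as black bars. Skeletal muscle markers range from 5.28 to 11.45 and are lowest in KO 1 and KO 3, whereas the 2 groups overlap in every panel.

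These 5 lists were the ones called by camera with its preset correlation among 39 tested, and 0 were called with an estimated correlation, by fry, or by exact permutation of list means. With the muscle covariate 10 lists were called with the preset correlation and 0 with an estimated one. A sign of RNA quality also differed between groups: the signal of the 3' control probe set of Pcx minus that of its 5' probe set was 2.88 ± 0.07 (SD, n = 5) in arrays labelled KO and 3.25 ± 0.20 (SD, n = 5) in WT. All KO values lay below all WT values (exact permutation p = 0.0079, the smallest that 5 against 5 arrays can give; 0.040 adjusted over 5 transcripts). The same measure differed by 0.05 for Actb, -0.02 for Gapdh, -0.08 for Tfrc and -0.15 for 18S RNA, and none of those passed.

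Genes of mitochondrial fuel use and heat production did not shift as groups in arrays labelled KO. Ucp1, the uncoupling protein of brown fat, differed by -0.08 ± 0.061 (-0.047 without KO 3, -0.022 without WT 4 and WT 5). In the thermogenic list (17 members, 12 lower, median -0.05, adjusted p of camera 0.61), Elovl3 differed by -0.63 ± 0.35 (-0.35 without KO 3) and Fgf21 by 0.20 ± 0.099. Fatty acid oxidation genes had a median of -0.04 (adjusted p of camera 0.31), with Etfdh at -0.14 ± 0.066 and Eci1 at -0.18 ± 0.095. Breakdown of branched-chain amino acids had a median of -0.05 (0.20), with Bcat2 at -0.42 ± 0.20 and Dbt at -0.24 ± 0.13. It reached an adjusted p of 0.0017 with the muscle covariate, 0.0020 without the 3 arrays lowest in muscle transcripts, 0.011 without KO 3 and 0.0083 with the mean of all probe sets, against 0.66, 0.91, 0.80 and 0.84 with an estimated correlation in the same 4 fits. Without WT 4 and WT 5, Bcat2 differed by -0.14 and Dbt by -0.089. Known SIRT3 substrates had a median of -0.014 (0.51), with Acss1 at -0.18 ± 0.073 and Foxo3 at -0.15 ± 0.10 (-0.082 and -0.017 without WT 4 and WT 5, and Foxo3 at -0.056 without WT 4). Medians and adjusted p of camera were -0.0020 and 0.75 for the TCA cycle (Fh1 at 0.05 ± 0.053, Suclg1 at 0.04 ± 0.046), -0.018 and 0.97 for pyruvate handling, -0.016 and 0.62 for complex I (Ndufb1 at -0.12 ± 0.046, Ndufv2 at -0.08 ± 0.047), -0.020 and 0.75 for complex III, -0.028 and 0.31 for complex IV (Cox4i2 at -0.12 ± 0.060, Cox7c at -0.25 ± 0.14), and -0.025 and 0.74 for complex V. They were -0.0050 and 0.82 for mitochondrial chaperones and proteases, 0.0060 and 0.47 for antioxidant defence (Gpx1 at 0.24 ± 0.097, Srxn1 at 0.24 ± 0.11) and -0.07 and 0.31 for hypoxia sensing (Hif1an at -0.16 ± 0.079, Egln2 at -0.09 ± 0.062). In complex IV, 14 of 17 members were lower, with a mean of -0.082 (-0.090 without WT 4 and WT 5). The exact permutation p of its list mean was 0.024, the smallest of the lists, and 0.84 adjusted over them. That list holds Cox6a2, which had r = 0.96 with the mean of the muscle list. Cox7c was at -0.074 without WT 4 and WT 5. Its probe set had a mean log2 signal of 5.81, against a complex IV list mean of 11.09 in WT arrays.

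Lipid, stress and regulatory groups gave medians and adjusted p of camera of 0.09 and 0.14 for lipogenesis (Me1 at 0.51 ± 0.24, or 0.11 without WT 4 and WT 5, Elovl5 at -0.24 ± 0.11), -0.05 and 0.20 for adipocyte lipid storage, and -0.0072 and 0.82 for cholesterol synthesis. For the integrated stress response they were -0.04 and 0.82; Atf3 passed adjusted over the list alone and Asns was at -0.19 ± 0.085. The circadian clock gave -0.03 and 0.65 (Nr1d1 at 0.19 ± 0.13, Npas2 at 0.09 ± 0.064) and reached an adjusted p of 0.0023 without WT 4 and WT 5, where its mean turned from -0.018 to 0.14; with an estimated correlation in that fit the adjusted p was 0.62. The interferon response gave 0.04 and 0.18, the cell cycle -0.03 and 0.82, the proteasome 0.0033 and 0.75, and the sirtuins 0.0080 and 0.50. Lipogenesis reached 0.011 with the muscle covariate, 0.0040 without WT 1, 0.018 without KO 3 and 0.029 without KO 5, but each of these calls was lost with an estimated correlation in the same fit (0.68, 0.87, 0.80 and 0.83), and without WT 4 and WT 5 the list mean turned from 0.11 to -0.064 (0.80). The proteasome reached 0.0021 with the covariate and 0.0041 without the 3 arrays lowest in muscle transcripts (0.66 and 0.91 with an estimated correlation in those fits), and the interferon response reached 0.0066 without WT 1 (0.87 with one).

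Markers of other cell types gave medians and adjusted p of camera of 0.04 and 0.18 for white adipocytes, of which Trem2 (0.21 ± 0.060, but 0.0094 in a second probe set) passed adjusted over the list alone and Lep, which encodes leptin, differed by 1.5 ± 0.77 (0.29 ± 0.56 without WT 4 and WT 5, where the list mean turned from 0.21 to -0.057). Macrophage markers gave -0.02 and 0.65, with Cd163 at -0.73 ± 0.29 and Mrc1 at -0.25 ± 0.10. Of the macrophage members 9 were higher and 10 lower, with differences up to 0.78. Without WT 4 and WT 5, Cd163 differed by -0.32 ± 0.23 and the mean of that list turned from -0.018 to 0.038. Medians and adjusted p of camera were 0.03 and 0.68 for T and B lymphocytes, -0.05 and 0.61 for neutrophils, 0.05 and 0.51 for fibroblasts and collagens, -0.00016 and 0.75 for smooth muscle and mural cells, and -0.0062 and 0.63 for nerve and Schwann cells. They were -0.09 and 0.18 for mast cells, -0.03 and 0.18 for thymus and lymphoid organs, and -0.06 and 0.31 for sex-linked transcripts. The erythroid list had 4 measured members (median 0.0083) and was not tested. Fibroblast (0.018) and thymus (0.047) markers were called with the muscle covariate, and neither with an estimated correlation in that fit (0.66 for both). Without 1 array, calls appeared for fibroblast markers (0.014 without KO 1), mast cells (0.031 without KO 2), white adipocytes (0.035 without WT 2) and macrophages (0.033 without KO 5). With an estimated correlation 0 lists were called in any of the fits that left out arrays. Median, mean and test differed in sign for the TCA cycle, the integrated stress response, the circadian clock, smooth muscle and nerve markers.

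Genes next to Sirt3 did not differ more often than other genes between arrays labelled KO and WT. Such genes can carry alleles of another substrain in a knockout. Among the 50 measured genes on each side, 5 of 100 had an unadjusted p under 0.05, or 5%, against 845 of 18092 other genes, or 4.67% (two-sided Fisher's exact test, p = 0.81). No gene among them was called. The count was 11 of 100 both without WT 2 (Fisher's exact p = 0.26) and with the muscle covariate (Fisher's exact p = 0.36), where the count over all genes was higher too, and 3 of 100 without KO 4.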

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

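The tests below were chosen after the results they bear on were seen, except the other splits of the arrays, the second list of muscle transcripts and the search for single arrays far from their group; the fits that left out 1 array were planned, and their use as a test was not. In 266 groups of 5 values (named genes, list means and 3'/5' measures of the 2 genotypes), 8 held an array far from the other 4, or 3.01%, where chance gives about 1 in 20. Fosl2 was 8.34 in KO 4 against 7.47 to 7.66 in the other KO arrays, Ier3 was 7.91 in KO 3 against 8.68 to 8.89, Elovl5 was 11.66 in KO 2 against 11.11 to 11.25, and Zfp955a was 6.77 in KO 2 against 6.50 to 6.55. Among WT arrays, Lyrm9 was 6.72 in WT 2 against 6.40 to 6.49, Fam162a was 11.05 in WT 5 against 10.88 to 10.93, Rpl39 was 7.74 in WT 3 against 7.93 to 7.97, and the interferon list mean was 6.36 in WT 1 against 6.12 to 6.17. Outside the genes tested, the 3' minus 5' control signal of Pcx was different by -0.37 log2 units in arrays labelled KO; the 5' probe set differed by 0.31 and the 3' probe set by -0.06.

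Of the 126 ways to split the 10 arrays into 5 and 5, 100 were drawn, the real one included. All 100 gave at least the 0 genes past the adjusted threshold of the real split, as any split must, so this count cannot test chance. The highest other split gave 204. That split set WT 1, WT 2, WT 3, KO 2 and KO 4 against the rest, whose means of the muscle list differed by 3.50 log2 units, against 1.53 in the real split, so that split follows a structure of the samples other than genotype. A second split, of WT 1, WT 2, KO 1, KO 3 and KO 4 against the rest, gave 57 genes; its muscle means differed by 0.83, less than in the real split. It divides the arrays by the sign of the second principal component (6.72 to 17.2 in those 5, -22.7 to -1.66 in the rest). Compared after the values were seen, Lep was 9.46 to 10.23 in those 5 and 5.75 to 8.82 in the rest. The mean of the white adipocyte list, which holds Lep, was 6.62 to 6.85 and 5.84 to 6.48. What drives that component was not tested and stays open. For the 851 genes at an unadjusted p under 0.05, 42 of the 100 splits gave as many, with a highest other of 2491, from that second split. For the 5 lists called by camera, 62 gave as many, with a highest other of 15 and a median of 5, so chance cannot be excluded for either count.

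Skeletal muscle markers were lower by 1.53 log2 units on average in arrays labelled KO, and Acta1, an abundant one, ranged from 6.21 to 13.9 over the arrays. Genotype as the only source is argued against by 3 of the 5 KO arrays lying inside the range of the WT arrays. A candidate explanation is skeletal muscle carried over with the fat pad in differing amounts. In a second list of 23 muscle transcripts, the median correlation with the mean of the first list over the 10 arrays was 0.93 (median rho 0.90). It was 0.95 without KO 1 and KO 3, the 2 arrays farthest from the median. The means of both lists had r = 0.97 (permutation p = 1e-05, the smallest that the 100000 random permutations drawn can give) and rho = 0.94 (permutation p = 0.00028). These were the only 2 relations tested. Of the 23 transcripts 5 had r below 0.2: Mybph (0.19), Fhl3 (-0.0072), Fbp2 (-0.10), Kbtbd13 (-0.36) and Trim72 (-0.78). Both lists would move together whatever changed the muscle RNA, so these correlations cannot tell carried-over tissue from another source. A part of the difference that comes from genotype stays open, as does chance.

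Immediate early and heat shock genes were higher by 0.47 log2 units on average in arrays labelled KO. With 1 array left out, the difference ranged from 0.35 (without KO 4) to 0.67 (without WT 1), and the muscle covariate did not lower it. The observed size therefore did not rest on 1 array alone or on the muscle mean alone. Given the intervals below, a part from differing muscle RNA or from a single array stays open. The difference was 0.53 with the muscle covariate, with an adjusted p of camera of 0.0023 (0.66 with an estimated correlation) and a 95% confidence interval of -0.18 to 1.23. Over all arrays without the covariate the interval already covered 0 (-0.14 to 1.09). An interval that covers 0 after the covariate or without 1 array therefore cannot decide on either explanation. The adjusted p of camera was at most 0.039 over the 10 fits that left out 1 array, the highest being without KO 4, but with an estimated correlation the list was called in 0 of them, and the interval of the mean difference lay above 0 only without WT 1 (0.18 to 1.15). Handling of animals or tissue before freezing could also move these genes, and it cannot be told apart from genotype because no time or order of collection is given in the sources used here. The exact two-sided permutation p of the list mean, 0.13, leaves chance open as well. Genotype remains an untested biological explanation.

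Sirt3 signal was not lower in arrays labelled KO. Exchanged labels, with a probe set that reads the deleted part, would leave some arrays far below the others, and the range of all 10 was 0.37 log2 units. A probe set outside the deleted part is a candidate explanation that cannot be told apart here from KO mice that keep the transcript, because the position of the deletion is not given in the sources used here; the difference was 0.19 log2 units in the direction of the KO arrays.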

How the results depend on the processing

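The covariate for muscle transcripts and the fits without named sets of arrays were chosen after the data were seen; the other settings were planned. Under every setting run, 0 genes passed the adjusted threshold, and no named gene was called. Of 1714 alternative differences of 87 named genes other than Sirt3, 38 turned in sign, in 10 genes; no list was called in the opposite direction. The 851 genes at an unadjusted p under 0.05 became 469 among the brighter genes (9096 tested) and 2444 over all 45037 probe sets, as fewer or more were tested. They became 1521 with the muscle covariate and ranged from 611 (without KO 4) to 1418 (without WT 2) when 1 array was left out. The 5 lists called became 3 without probe sets named _s_at, _x_at or _a_at, 10 with the muscle covariate, 0 with an estimated correlation and 0 by fry, and ranged from 3 (without WT 5) to 7 (without WT 1, KO 3 or KO 5) when 1 array was left out. The adjusted p of glycolysis became 0.029 with the muscle covariate and ranged from 0.037 (without KO 3) to 0.66 (without WT 5) when 1 array was left out; it was 0.87 with an estimated correlation and 0.98 without WT 4 and WT 5. The Sirt3 difference, 0.19, passed an unadjusted exact permutation test and was 0.13 without WT 4 and WT 5. In that fit 30 of the 87 other named genes kept less than 0.5 of their difference or turned in sign, and the means of 13 of the 39 tested lists turned in sign. With 1 array left out, 17 of these genes and 27 of the lists had a fit with less than 0.5 of the difference or the other sign. The cause of these changes was not tested, except where the number tested changed.

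Signs turned in Sirt7 with centred arrays (-0.0037), in Sirt4 (-0.0088) and Pdk1 (-0.0011) with array weights, and in Slc2a1 (0.0043), Pdk1 (-0.0083) and Vegfa (0.056) with the mean of all probe sets. They also turned in Slc2a1 (0.013) and Hif1a (-0.042) without probe sets named _s_at, _x_at or _a_at and in Sirt4 (-0.00020) and Slc2a1 (0.041) with the muscle covariate. Without WT 4 and WT 5 they turned in Sirt1 (0.040), Sirt5 (-0.040), Sirt7 (-0.0022), Slc2a1 (0.023), Pdk1 (-0.070), Vegfa (0.059) and Pkm (-0.020). With 1 array left out, the differences ranged from -0.12 (without WT 2) to 0.0043 (without WT 4) for Sirt1, -0.027 to 0.043 for Sirt4, -0.056 to 0.045 for Sirt7, -0.12 to 0.092 for Slc2a1, -0.10 to 0.034 for Hk2, -0.014 to 0.065 for Pdk1 and -0.089 to 0.020 for Vegfa.

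Replicate numbers did not pair the arrays. After the mean of each gene within its genotype was subtracted, same-numbered arrays had correlations of -0.12, 0.24, -0.40, -0.27 and 0.014. With the replicate number as a block, 0 genes passed, 736 had an unadjusted p under 0.05, 5 lists were called and Sirt3 differed by 0.19. Arrays without a detection call leave open how far dim transcripts lie above background.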

Other observations

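WT 4 and WT 5 stood apart from the other arrays on the second principal component, which held 19.9% of the variance, at -22.7 and -17.4, where the other 8 lay between -7.71 and 17.2. The transcripts named here were chosen after their values were seen, for their spread. Mfsd2a, a lipid transporter, was 10.21 and 10.50 log2 units in WT 4 and WT 5, 7.43 in KO 5 and between 4.72 and 5.62 in the other 7 arrays. Cyp2e1, a cytochrome P450, was 11.53 and 10.13 in WT 4 and WT 5 and at most 8.68 elsewhere. Fkbp5 and Zbtb16, known to respond to glucocorticoids, were 10.54 and 11.05 in WT 4, 8.74 and 10.25 in WT 5, and 8.78 and 10.32 in KO 5. Rab6b was 4.47 and 4.39 in WT 4 and WT 5 and at least 7.21 elsewhere, and leptin (Lep) was 6.34 and 5.75 there and at least 7.92 elsewhere.

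Fos ranged from 4.49 (WT 5) to 11.53 (WT 1) and Egr1 from 6.39 (WT 5) to 11.24 (WT 1), spans of 7.04 and 4.85 log2 units. The probe set of Xist with the highest signal was 7.39 in WT 3 and 7.35 in KO 4, against 5.59 to 5.89 in the other 8 arrays, while Eif2s3y, on the Y chromosome, was between 9.39 and 9.68 in all 10.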
